A study of Mus musculus with 10 samples.

How the data were processed

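The series compared cultured cortical neurons from E14 mouse embryos of the ICR strain, collected at day 11 in vitro, after delivery of either a control adeno-associated virus (AAV-Control) or one carrying Gata1 (AAV-Gata1). It lists 10 samples. For 4 of them processed values were at hand: 1 mRNA library and 1 small RNA library from each condition. The other 6, which are H3K4me3 and H3K27me3 chromatin immunoprecipitations and input DNA, were not analysed here. Total RNA was taken with a miRNeasy kit, mRNA libraries were made with a TruSeq Stranded mRNA kit for paired-end reads, and small RNA libraries with a NEXTFLEX Small RNA-seq kit with gel selection of the product, per the labels' protocols.

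The deposited mRNA values are FPKM (fragment counts divided by transcript length and by the number of mapped fragments), per the file headers. TopHat2 2.1.1, Cufflinks 2.1.1 and Cuffdiff 2.1.1 are among the tools named, per the submitters' processing notes, which also name BWA, HOMER, Bowtie 1.1.2, HTSeq 0.6.1p1 and edgeR 3.10.2 and the mouse builds mm9 and mm10, without saying which served which assay. Whether fragments were counted by strand, and whether the FPKM were scaled further between libraries, is not given in the sources used here. Each mRNA table held 40993 rows, of which 6 carried no gene symbol. Those rows made up 0.0122% of the summed FPKM in the control and 0.0113% in the Gata1 library and were left out. Where a symbol had several rows, the row with the highest mean was kept. The low FPKM values were searched for steps of whole fragments: of 1201 genes above 0 and under 0.1 FPKM in both libraries, no more than 37 shared a log2 ratio to within 0.02, so no relative depth was recovered and the depth of the mRNA libraries is unknown.

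The deposited small RNA values are CPM (read counts scaled to a common library total); the file headers call them normalized counts, and each column sums to 1000000. All of the values above 0 (100% in both libraries, within a tolerance of 0.0055 CPM) were whole multiples of 1 step per library, so read counts were recovered. They total 15632553 in the control and 12644419 in the Gata1 library over all rows. The tables give 1 row per mature microRNA and precursor, and rows of 1 mature name hold nearly the same reads again: with only the highest row of each of the 1915 mature names kept, as was done here, the totals are 7741365 and 6314572. CPM was left as deposited, relative to the sum over all rows.

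With 1 library per group no test between conditions was possible, and differences have no replicate check. For each gene the value compared was log2((Gata1 + 1)/(control + 1)) of the FPKM, for genes with a mean of at least 1 FPKM. This scale understates differences of genes with low values. Genes at least 2-fold apart on it were counted as a rule of size. For each microRNA with at least 20 reads over both libraries the CPM ratio is given with an exact (Clopper-Pearson, conditional binomial) 95% interval. These intervals compare the reads of 2 libraries, not the conditions, and cover counting error only, since reads amplified by PCR are not independent molecules. The ratios, the intervals and the counts past 2-fold used the reads without a floor. In the microRNA lists described below, a count of 0 was given a floor of 3 reads, which is 0.192 CPM in the control and 0.237 CPM in the Gata1 library.

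Gene lists were fixed before the data were examined. A list with at least 5 measured members was summarised by its median log2 ratio, set against the medians of 10000 random lists of the same size matched on mean expression in 10 bins. Lists outside the 2.5th to 97.5th percentile are called apart from the random lists, as a description of these libraries. Of 39 lists that could be summarised, 1.95 would lie outside by chance if members varied as independently as genes drawn at random. Members of a pathway or cell type can vary together between cultures, so the number of called lists cannot be read against it. Genes were named by a rule fixed at the same time. It took Gata1, then the 12 largest differences in each direction among named genes (predicted genes, clones and small RNA genes left out) reaching 5 FPKM in 1 of the libraries, and up to 4 members of each list by size, or all members of a list of 6 or fewer. For microRNAs it took the 8 largest ratios in each direction at a mean of at least 100 CPM, the 5 most abundant, and up to 4 members of each list. Any gene named outside the rule is said to be so.

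On simulated libraries with the 12235 named genes, 200 genes with a mean of at least 5 FPKM were altered in each run. All were counted past 2-fold when altered 3-fold (100%), and none when altered 1.5-fold (0%). The simulated spread was small beside the distance of both alterations from the 2-fold limit. These 2 rates therefore follow from the settings, and check the counting alone. Genes below that mean were not altered, so their recovery is not known. Lists of 40 genes lowered by 0.1 on the log2 scale were called in 100% of draws, and lists with no shift in 8%. The simulated genes varied independently with the same spread, so neither rate need hold for lists of genes that vary together. Simulated microRNA ratios lay inside their intervals for 94.1% of 563 microRNAs. Alternatives covered pseudocounts, expression minima, scalings, the fold limit and the way random lists were drawn; those chosen after the data were seen are named as such in the closing section. Gene spans and overlaps came from a RefSeq table of assembly GRCm38.p6, whose coordinates are not printed here; 96.2% of the named genes had a span there. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone.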

Results

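The mRNA and the microRNAs of mouse cortical neurons were profiled after delivery of Gata1, a zinc finger transcription factor that drives red cell and platelet development, and after delivery of a control virus. The series pairs these profiles with histone modification profiles, which were not analysed here. Each condition had 1 mRNA library and 1 small RNA library, so none of the differences below has a replicate check and none was tested. The mRNA libraries summed to 476398 FPKM (control) and 476848 FPKM (Gata1), with 13748 and 13704 genes at 1 FPKM or more. The small RNA libraries held 7741365 (control) and 6314572 (Gata1) reads with 1 row per mature microRNA. Over all precursor rows, which repeat many of these reads and set the CPM scale, the totals were 15632553 and 12644419.

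Gata1 itself was listed at 0 FPKM in the control and at 2.07 FPKM in the Gata1 library, so the values go the way of the labels. The level was low. In the Gata1 library 12439 genes had a higher FPKM, and Gata1 stood at the 7.27th percentile of the named genes that could be compared. Otherwise the libraries were close: over 12235 named genes the Pearson correlation of log2 values was 0.996, across genes, which are not independent replicates, and 94.9% of those genes lay within 1.2-fold.

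Among named genes the list of large differences was short. Of those 12235 genes, 5 were at least 2-fold higher and 7 at least 2-fold lower in the Gata1 library. The higher ones, which were named here in full after their values were seen, were Gata1, Hist2h3c1 (0.0356 to 4.09 FPKM), Clvs2 (1.80 to 4.85 FPKM), the noncoding gene Yam1 (174 to 349 FPKM) and Sardhos (4.59 to 10.5 FPKM). Among genes reaching 5 FPKM, Efcab7 followed (12.1 to 23.5 FPKM), and further down came Ms4a6c and Fcgr2b, genes of myeloid cells, the latter an inhibitory receptor for antibodies (3.80 to 6.08 FPKM and 4.39 to 6.59 FPKM). The transcription factor gene Cebpb stood at 8.25 and 12.1 FPKM, and Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, at 17.0 and 25.3 FPKM. The rest of the 12 largest higher values were those of Tmem53, Dnase1l1, Wdr17, Mrpl47 and Mthfs.

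On the lower side, Auts2, a gene of neuronal development, stood at 25.0 FPKM in the control and 9.57 FPKM in the Gata1 library. Rint1, which acts in membrane traffic between the Golgi and the endoplasmic reticulum, stood at 16.2 and 6.21 FPKM, the RNA-binding protein gene Khdrbs2 at 6.41 and 2.80 FPKM, and Apbb2, whose product binds the amyloid precursor protein, at 14.4 and 7.04 FPKM. The 7 lower genes past 2-fold were Dlx6os1, Auts2, Rint1 and, named after their values were seen, B3gnt2 (2.60 to 0.508 FPKM), Sp140 (3.40 to 1.09 FPKM) and the pseudogenes Eif3s6-ps2 (4.65 to 1.13 FPKM) and Rpsa-ps2 (3.74 to 1.02 FPKM); Khdrbs2 and Apbb2, more than 2-fold apart in FPKM, pass that limit with a pseudocount of 0.1 but not with the pseudocount of 1 used here. Dlx6os1, a noncoding gene beside the Dlx5 and Dlx6 homeobox genes, was listed at 21.5 FPKM in the control and at 0 in the Gata1 library in 1 of its 2 rows, while its other row read 9.90 and 10.7 FPKM. The rest of the 12 largest lower values were those of Atf7ip, Fam134a, Stag3, Chic2, Cd99, Nkain2 and Swt1. Of the 21 of these 24 genes with an annotation, 12 (57.1%) overlap another gene, where reads can be assigned to either, against 47.5% of all 9422 annotated named genes at this level. Auts2, Khdrbs2, Apbb2, Dlx6os1, Efcab7, Ms4a6c and Lars2 are among those 12. Rint1, Cebpb and Fcgr2b overlap no other gene.

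Over all 13740 genes compared, 32 were at least 2-fold higher and 39 at least 2-fold lower. Most of these were not named protein-coding genes. Predicted genes and clones gave 20 and 23 of them, and small RNA genes 7 and 9, out of 21 small RNA genes compared. In 23 of the 32 the control value, and in 23 of the 39 the Gata1 value, was under 0.01 FPKM. Without genes under 0.01 FPKM in either library the counts were 9 higher and 16 lower, a setting chosen after the data were seen.

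**Figure D1:**
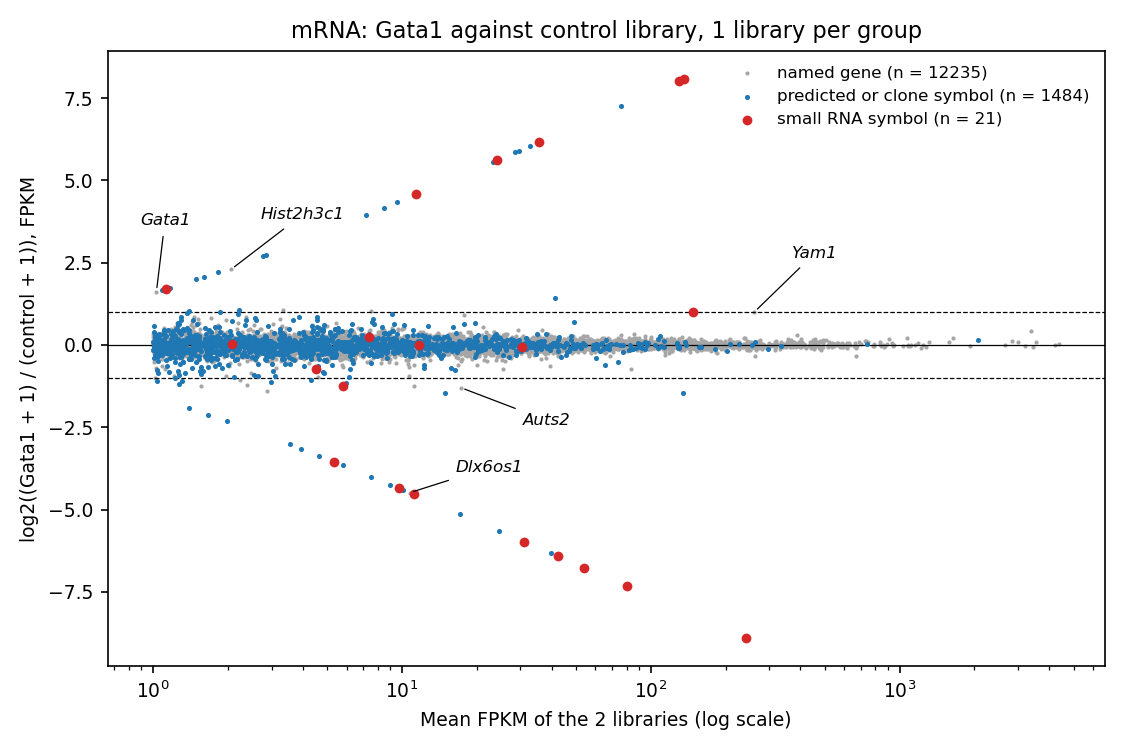
Difference of each gene between the Gata1 and the control mRNA library, as log2((Gata1 + 1)/(control + 1)) of FPKM, against the mean FPKM on a log scale. Each point is 1 of 13740 genes, coloured by the class of its symbol, and dashed lines mark 2-fold; the points far from 0 are mostly predicted genes and small RNA genes, and 5 named genes lie above the upper line.

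Vesicle and glutamatergic postsynaptic genes were lower in the Gata1 library by small amounts that went the same way in most members. Of 41 measured genes of synaptic vesicles and transmitter release, 37 were lower, with a median log2 ratio of −0.11 (7.27% lower), below all of the random lists. Examples are the vesicle protein gene Sv2c (3.02 to 2.19 FPKM), the vesicle GTPase gene Rab3b (19.97 to 15.81 FPKM), the release factor gene Unc13a (14.4 to 11.8 FPKM) and Syn3 (6.59 to 5.38 FPKM). Of 44 glutamatergic postsynaptic genes 36 were lower, with a median of −0.092 (percentile 0.01), among them Homer3 (19.0 to 15.4 FPKM), the kainate receptor gene Grik4 (5.46 to 4.32 FPKM) and the AMPA receptor gene Gria4 (10.3 to 8.75 FPKM). The 5 neuronal genes that earlier work linked to GATA1 in cortex were all lower, at a median of −0.14 (percentile 0.16): Tubb4a stood at 62.6 and 53.1 FPKM, Rab4b at 22.9 and 19.9, Syn1 at 34.1 and 30.8, Rab3a at 99.2 and 92.6, and Calm2 at 409 and 390 FPKM. Syn1 and Rab3a also belong to the vesicle list. With means in place of medians the vesicle list (−0.11, percentile 5.58) and the postsynaptic list (−0.090, percentile 5.08) came inside the range of random lists drawn from all genes; against random lists of named genes, a setting added after the data were seen, both means stayed below it (percentiles 0.13 and 0.77).

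Voltage-gated channel genes were lower in 28 of 40 cases, at a median of −0.067 (percentile 1.28), with Cacna1g (5.36 to 3.91 FPKM) and Kcnq3 (3.05 to 2.30 FPKM) furthest apart. With genes under a mean of 5 FPKM left out, their median was −0.0041 and lay inside the random range. GABA receptor genes and their scaffold had a median of −0.029 (percentile 26.7), with 16 of 21 lower. Early genes induced by neuronal activity had a median of 0.015 (percentile 84.8), with Fos at 16.05 and 21.47 FPKM. Genes of neurotrophins and growth had a median of −0.033 (percentile 22.2); Igf1, which microglia also express, stood at 20.3 and 26.7 FPKM and Vgf at 6.41 and 5.03 FPKM. Beside these groups, microglia markers were higher and oligodendrocyte and pericyte markers lower, as given next.

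Markers of cell types did not move together. Pan-neuronal markers were lower in 14 of 15 cases, at a median of −0.086 (percentile 0.12), among them Eno2 (40.7 to 36.5 FPKM) and Elavl3 (50.3 to 45.5 FPKM). Markers of excitatory neurons (median −0.018, percentile 46.4; Slc17a6 at 4.51 and 3.70 FPKM) and of inhibitory neurons (median 0.020, percentile 83.8; Pvalb at 0.841 and 1.53 FPKM) lay inside the random range. All 17 microglia markers were higher, at a median of 0.21 (15.8% higher), above all of the random lists. They include the protease gene Ctss (22.8 to 29.1 FPKM), the chemokine receptor gene Cx3cr1 (14.6 to 18.2 FPKM), Lyz2 (68.2 to 83.5 FPKM) and the lipid receptor gene Trem2 (43.7 to 53.4 FPKM). Oligodendrocyte lineage markers were lower in 11 of 15 cases, at a median of −0.10 (percentile 0.47), among them Enpp2 (9.73 to 8.01 FPKM) and Gpr17 (15.2 to 12.6 FPKM). Pericyte and fibroblast markers were lower in 7 of 8 cases, at a median of −0.14 (percentile 0.43), with the smooth muscle actin gene Acta2 at 76.4 and 60.7 FPKM; their mean, −0.11, lay inside the range of random lists (percentile 6.13). Astrocyte markers (median −0.028, percentile 13.0; Slc4a4 at 37.9 and 31.7 FPKM) and progenitor markers (median −0.0021, percentile 59.99; Hes1 at 11.3 and 13.7 FPKM) lay inside the range. Only 3 endothelial markers were measured, Egfl7 (4.46 to 5.08 FPKM), Slco1a4 (3.98 to 3.56 FPKM) and Kdr (2.444 to 2.197 FPKM), and no median was taken.

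Known targets of GATA1 in blood cells showed no shared difference. Of 54 erythroid targets, 19 were measured, with a median of −0.020 (percentile 42.0) and no member 2-fold apart; Slc25a37, the mitochondrial iron importer gene, stood at 5.12 and 4.65 FPKM and the embryonic globin gene Hbb-y at 4.07 and 4.36 FPKM. Of 33 targets in megakaryocytes and mast cells 7 were measured, with a median of 0.088 (percentile 96.8), inside the range. Within this list Itga2b, the platelet integrin gene, stood at 1.39 and 3.34 FPKM and Pf4, platelet factor 4, at 3.84 and 5.70 FPKM. With the mean in place of the median this list stood apart, at 0.19 (percentile 99.3), while a minimum mean of 5 FPKM, which leaves out Itga2b and Pf4, turned its median to −0.044 over 5 genes (percentile 25.2). Genes of heme synthesis and iron had a median of 0.030 (percentile 95.2), with the heme oxygenase gene Hmox1 at 149 and 170 FPKM. GATA factors and their partners had a median of −0.037 (percentile 23.1); in this list Spi1, the myeloid factor PU.1, stood at 3.44 and 4.61 FPKM and Lmo1 at 15.8 and 13.0 FPKM.

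Genes of the interferon and innate response were higher in 19 of 23 cases, at a median of 0.083 (percentile 99.7), beside the higher microglia markers. Examples are the immunoproteasome gene Psmb9 (1.51 to 2.28 FPKM), Ifi35 (1.18 to 1.82 FPKM) and Bst2 (6.57 to 8.32 FPKM). Apoptosis genes were higher in 19 of 25 cases, at a median of 0.054 (percentile 99.6), among them the caspase genes Casp8 (1.07 to 1.45 FPKM) and Casp6 (10.4 to 11.9 FPKM). Cholesterol synthesis genes had a median of 0.040 (percentile 97.8), with 12 of 21 higher; Sc5d stood at 19.6 and 23.0 FPKM and Fdps at 29.6 and 26.7 FPKM. This call ended with genes under a mean of 5 FPKM left out (0.038, inside the range). With means in place of medians, 8 of the 11 called lists came inside the range of random lists: those of synaptic vesicles, the glutamatergic postsynapse, voltage-gated channels, apoptosis, cholesterol synthesis, and pan-neuronal, oligodendrocyte and pericyte markers.

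The remaining lists lay inside the range of random lists. Chromatin genes had medians of −0.049 for PRC2 and the H3K27 demethylases (percentile 15.1; Aebp2 at 25.3 and 22.7 FPKM) and −0.035 for the H3K4 methyltransferases and demethylases (percentile 18.7; Kmt2a at 11.5 and 10.1 FPKM). Genes of microRNA processing had a median of −0.019 (percentile 41.4), with Ago3 at 4.90 and 3.97 FPKM and Dgcr8 at 13.8 and 12.1 FPKM. The medians were 0.0029 for p53 targets (percentile 72.3), 0.0044 for the ATF4 and unfolded protein response (percentile 78.6), 0.020 for cell cycle genes (percentile 88.8), 0.013 for cytosolic ribosomal proteins (percentile 92.5), 0.014 for nuclear-encoded respiratory chain subunits (percentile 94.5) and −0.0047 for proteasome subunits (percentile 48.4). No mitochondrially encoded gene was found in the tables as read here.

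**Figure D2:**
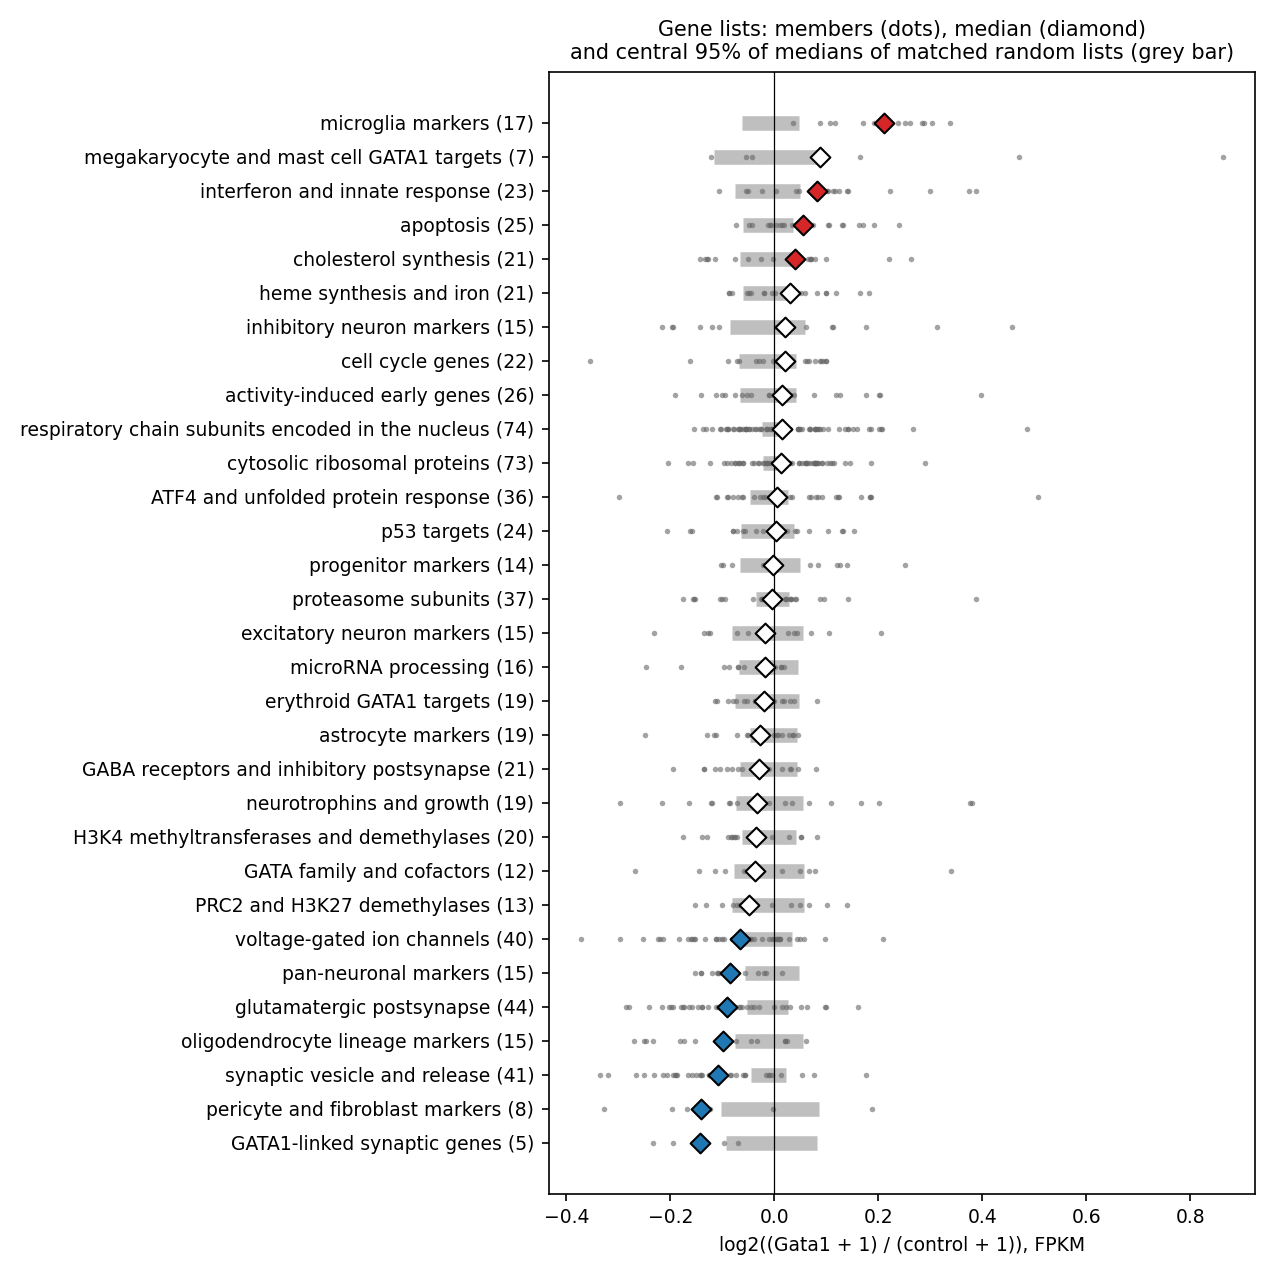
Gene lists ordered by the median log2((Gata1 + 1)/(control + 1)) of FPKM, with the number of measured members in parentheses. Dots are members, diamonds are medians (blue and red outside the central 95% of random lists, white inside) and grey bars span that central 95%; microglia markers lie highest, at 0.21, and the GATA1-linked synaptic genes lowest, at −0.14.

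MicroRNA profiles of both small RNA libraries were alike for all abundant species. None of 137 microRNAs with a mean of at least 100 CPM differed by 2-fold, and none by 1.5-fold. The most abundant, the neural microRNA miR-9-5p, made up 26.5% of the reads counted once per mature microRNA in the control and 25.0% in the Gata1 library (13.1% and 12.5% of the totals that repeat reads over precursor rows), a CPM ratio of 0.949 (95% counting interval 0.947 to 0.951). It was followed by let-7c-5p (ratio 1.05), let-7f-5p (0.999), the neuronal miR-128-3p (1.07) and let-7a-5p (1.06). The highest ratio among these 137 was that of miR-466i-5p, at 287 and 423 CPM (ratio 1.47, interval 1.42 to 1.53). The next were miR-3968 (1.25), miR-744-5p (1.25), miR-760-3p (1.24), miR-2137 (1.23), miR-488-3p (1.22), miR-125b-1-3p (1.195) and miR-370-3p (1.19). The lowest were miR-135a-5p, at 136 and 113 CPM (ratio 0.834, interval 0.779 to 0.892), miR-335-5p (0.838), miR-7a-5p (0.847) and miR-342-3p (0.861), followed by let-7j (0.889), miR-182-5p (0.890), miR-93-5p (0.895) and miR-7b-5p (0.897).

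Larger ratios were seen only at low counts. Of 563 microRNAs with at least 20 reads, 36 were at least 2-fold higher and 24 at least 2-fold lower, with a median of 41 reads over both libraries, and 53 of the 60 had fewer than 100. The interval lay wholly past 2-fold for 10 higher and 2 lower microRNAs. The lower ones, named after their values were seen, were miR-183-3p (21 and 1 reads, ratio 0.059, interval 0.0014 to 0.366) and miR-7068-3p (29 and 3 reads, ratio 0.128, interval 0.0249 to 0.413). Among the 10 higher ones was miR-7066-5p, also named after its values were seen (24 and 78 reads, ratio 4.02, interval 2.51 to 6.64). The exact count comparison of these libraries, added after the data were seen, gave an interval above 1 for 168 and below 1 for 109 of the 563; it says nothing of the spread between cultures. These counts hold for the deposited CPM scale only. Centring the ratios on their median, a log2 shift of 0.051, was not applied to the intervals.

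**Figure D3:**
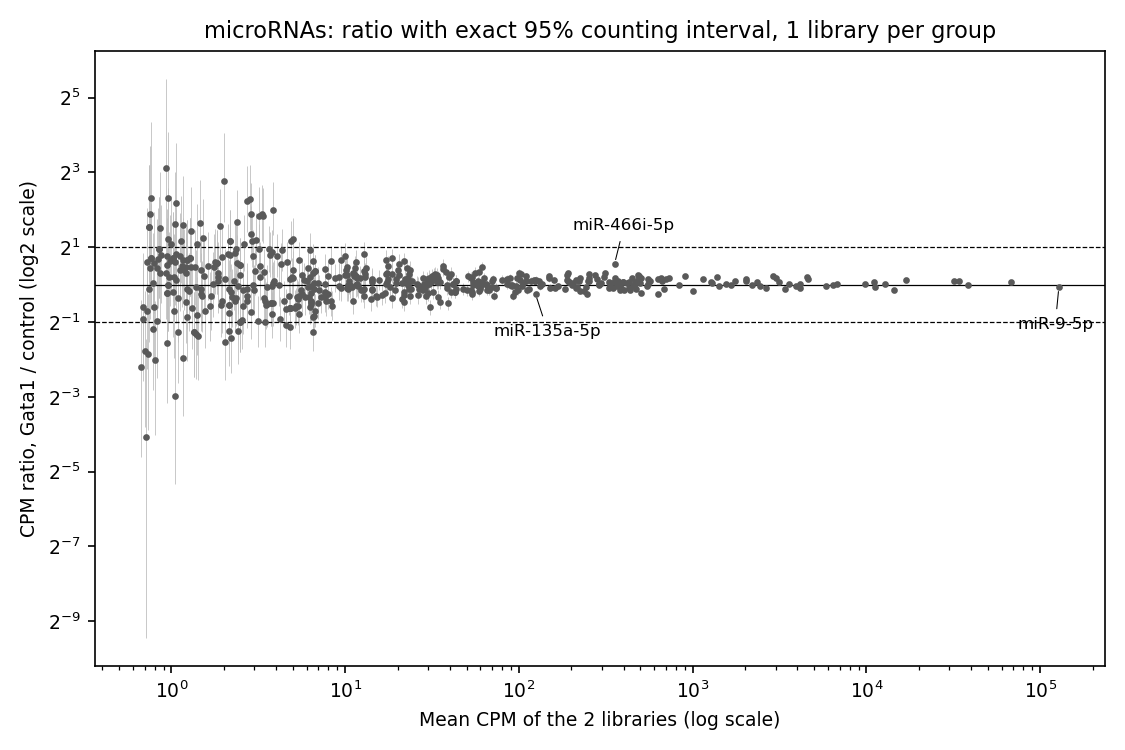
CPM ratio of each microRNA (Gata1 over control, log2 scale) against the mean CPM (log scale), for 562 microRNAs with at least 20 reads over both libraries and at least 1 in each. Bars are exact 95% intervals for counting error and dashed lines mark 2-fold; above 100 CPM all points lie between the dashed lines.

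No microRNA list stood apart from random lists by its median at the minimum of 20 reads. At a minimum of 100 reads, a setting added after the data were seen, the miR-17 to miR-92 clusters were lower (median −0.096, percentile 1.16) and neuron-enriched microRNAs higher (median 0.094, percentile 97.8), while the medians of activity-linked microRNAs (−0.019), the Dlk1-Dio3 cluster (0.024, percentile 34.4) and the miR-29, miR-34 and miR-200 families (−0.15) lay nearer 0. Centring the ratios on their median lowers each microRNA list median by the same amount and leaves its percentile as it is: with it the medians were 0.041 for neuron-enriched, 0.024 for erythroid, −0.12 for activity-linked and −0.094 for glial and myeloid microRNAs, 0.012 for the Dlk1-Dio3 cluster, −0.090 for the miR-17 to miR-92 clusters and −0.049 for let-7 and miR-98. The erythroid microRNAs had a median log2 ratio of 0.075 (percentile 73.4), although miR-451a, abundant in red cells, stood at 3.20 CPM in the control and 1.19 CPM in the Gata1 library. Neuron-enriched microRNAs had a median of 0.092 (percentile 94.5), with miR-128-1-5p at 1.60 and 4.11 CPM, and microRNAs linked to neuronal activity one of −0.072 (percentile 5.87), with miR-188-5p at 3.13 and 2.29 CPM. Glial and myeloid microRNAs had a median of −0.043 (percentile 10.7), with 6 higher and 11 lower. Among them the myeloid miR-142a-5p stood at 2.56 and 1.74 CPM, while the largest difference in the list was a rise, at a log2 ratio of 2.31. The medians were 0.0019 for let-7 and miR-98 (percentile 15.8), which turns negative with centring, −0.039 for the miR-17 to miR-92 clusters (percentile 8.86) and 0.063 for the Dlk1-Dio3 cluster (percentile 69.1). Names are not all independent: 42 of the 563 microRNAs have the same counts as another in both libraries. In the Dlk1-Dio3 list 7 of 76 microRNAs were at least 2-fold higher, among them miR-410-5p (1.41 to 4.98 CPM), miR-299a-3p (1.22 to 4.51 CPM) and miR-299b-3p (0.960 to 4.51 CPM). The last 2 have the same Gata1 count. The mean of the list, 0.19, stood apart (percentile 98.9). It includes miR-342-3p and miR-342-5p, both lower, whose place in the cluster was not checked. The miR-29, miR-34 and miR-200 families had a median of −0.26 over 11 microRNAs (percentile 12.7), with miR-34c-3p at 3.39 and 1.42 CPM and miR-34b-3p at 8.44 and 4.75 CPM. Members of this list went both ways, with 4 higher and 7 lower. The largest difference among them was a rise, at a log2 ratio of 1.254, against −1.252 for the largest fall.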

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

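The settings added after the data were seen are all rows, genes under 0.01 FPKM left out, named genes only, summed microRNA rows, the interval excluding 1, a minimum of 100 reads for the microRNA lists, and the random lists drawn from named genes or matched on span. Counts of mRNA genes at least 2-fold higher and lower (32 and 39) stayed within 1.5 times with a pseudocount of 0.5, no minimum, median-of-ratios or 75th percentile scaling, and all rows. They were 60 and 70 with a pseudocount of 0.1, 59 and 88 scaled to a sum of 1000000 (values grow against the pseudocount and the minimum), 80 and 96 at 1.5-fold, 18 and 23 at a minimum mean of 5, 9 and 16 without genes under 0.01 FPKM, and 5 and 7 among named genes. MicroRNA counts (36 and 24) stayed within 1.5 times under median of ratios, TMM, a total without the 5 most abundant, and summed rows. They were 214 and 165 with no minimum, 83 and 53 at 1.5-fold, 3 and 4 at a minimum of 100 reads, 10 and 2 with the interval wholly past 2-fold, and 168 and 109 with the interval excluding 1. All 11 called lists kept direction under each setting, and also their call with a pseudocount of 0.1, median of ratios, and random lists from named genes. A minimum mean of 5 ended the call of the channels (−0.0041) and cholesterol synthesis (0.038), and span matching that of cholesterol synthesis (0.0399). List means lost it for the vesicle (−0.115), postsynaptic (−0.090), channel (−0.077), apoptosis (0.0589), cholesterol (0.0147), pan-neuronal (−0.082), oligodendrocyte (−0.109) and pericyte (−0.114) lists; with random lists of named genes, which lack the extreme small RNA rows, means lost it for cholesterol synthesis (0.0147) and pericytes (−0.114) alone. Of the 28 lists inside the range, 2 came outside with means (26 did not), the respiratory chain list also with means against random lists of named genes (0.0246), and 2 of 8 microRNA lists with a minimum of 100 reads, the miR-17 to miR-92 clusters (−0.096) and the neuron-enriched microRNAs (0.094). Khdrbs2 and Apbb2 passed 2-fold with a pseudocount of 0.1; the other genes and microRNAs named for their size or abundance kept their side of 2-fold under the settings run on them. The cause of the other losses was not tested. No paired analysis was possible because each group has 1 library. Unknown mRNA depth leaves the counting error of low FPKM open.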

Other observations

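The tests of microRNA genes against mature microRNAs and of the neuron share, and the look at microRNA clusters, were chosen only after the results were seen. Genes and microRNAs named in this part that the naming rule does not give, such as Mir3473e, Mir760, Lgmn, Ctsz, miR-155-5p, miR-146a-5p and miR-223-3p, were chosen after their values were seen.

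Members of the miR-34 family, which p53 induces, were lower in the Gata1 library in 4 of 4 measured arms, 3 of them with a counting interval below 1. The most abundant, miR-34a-5p, had 710 and 407 reads (ratio 0.709, interval 0.626 to 0.802). The p53 target mRNAs had a median log2 ratio of 0.0029. Of the 7 microRNAs past 2-fold with at least 100 reads, miR-322-5p (144 and 48 reads, ratio 0.412, interval 0.291 to 0.575) and miR-542-3p (104 and 38 reads, ratio 0.452, interval 0.303 to 0.661) come from 1 cluster on the X chromosome. The cluster as a whole did not share this: 6 of its 11 measured arms had a ratio below 1, and miR-322-3p had 3337 and 2868 reads (ratio 1.06, interval 1.01 to 1.12). The others of the 7 were miR-1298-5p and miR-23b-5p, which were lower, and miR-3074-5p, miR-539-5p and miR-7066-5p, which were higher.

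The largest differences in the mRNA table sat in small RNA genes: 6 microRNA genes were past 2-fold, Mir3473e reading 482 FPKM in the control and 0 in the Gata1 library, and Mir760 reading 108 and 0 FPKM. If the microRNA itself changed, mature arms should follow, yet 0 of the 3 arms measured with at least 20 reads moved by 2-fold the same way, and their intervals exclude it; miR-760-3p had a ratio of 1.24 (interval 1.18 to 1.31). Among small RNA genes past 2-fold, 6 of the 7 higher were under 0.01 FPKM in the control, and 8 of the 9 lower in the Gata1 library. How many fragments lie behind these FPKM is unknown. A change of the precursor that leaves the mature form alone was not tested and stays open. For the 24 largest differences of named genes, reads shared with overlapping genes may play a part: 57.1% of the 21 annotated ones overlap another gene (Wilson 95% interval 36.5% to 75.5%) against 47.5% of all 9422 annotated named genes at this level, a ratio of 1.202, and the interval is too wide to decide. An effect of Gata1 on these genes was not tested.

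Vesicle and glutamatergic postsynaptic genes were lower in the Gata1 library. GABA receptor genes and their scaffold lay inside the random range (median −0.029), though 16 of 21 were lower. At a minimum mean of 5 FPKM their median was −0.051 (percentile 7.47), still inside it. Whether these lists differ from each other was not tested. Long genes were slightly lower as a class (median log2 ratio −0.034 in the tenth of genes with the longest spans, 0.0058 in the tenth with the shortest), but the vesicle list stayed at percentile 0 among random lists matched on expression and gene span, which argues against long genes lower as a class being the whole cause. Pan-neuronal markers were lower by a like amount (median −0.086), as a lower share of neurons in the culture would give. Markers of excitatory (median −0.018, percentile 46.4) and inhibitory neurons (median 0.020, percentile 83.8), which that share would lower too, lay inside the random range. That range reached down to −0.082 and −0.085 for these 2 lists, so a fall this small could hardly stand out in them. If the other cell types kept their proportions to each other, a lower share of neurons would also lift all of their markers alike. This was not seen: oligodendrocyte lineage markers had a median of −0.0995 and microglia markers a median of 0.21, both outside the random range. Astrocyte markers had a median of −0.028 (percentile 13.0), inside it. The shares of other cell types may differ as well, and these medians were known beforehand, so they cannot decide whether the neuron share was lower. A lower share of neurons stays open. An effect of Gata1, and a difference between these cultures unrelated to it, also stay open, as untested.

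Microglia markers were higher in 17 of 17 cases, none of them held by another list. Against random lists matched on expression and span, their median lay 0.1587 above the upper end of the central 95%. That argues against short genes, slightly higher as a class, being the whole cause. A larger share of microglia or macrophages in the Gata1 culture may account for the higher markers. A second list of 50 such genes, written before its values were examined apart from Spi1, had a median of 0.2094 over 42 measured genes (0.2077 without Spi1), above all random lists, with 37 higher and 5 lower and its most abundant genes Lgmn (142 to 156 FPKM) and Ctsz (79.8 to 88.8 FPKM) among the higher. Myeloid microRNAs went both ways and decide nothing: miR-155-5p had a CPM ratio of 0.830 (interval 0.704 to 0.977), while the intervals of miR-142a-5p (ratio 0.680, 0.385 to 1.17), miR-146a-5p (ratio 1.05, 0.956 to 1.16) and miR-223-3p (ratio 1.15, 0.497 to 2.63) include 1, and the glial and myeloid list had a median of −0.043 and a mean of 0.056, both inside the random range. That mean includes 1 member at a log2 ratio of 2.31. The larger share remains a hypothesis from the mRNA lists alone, and higher expression per microglial cell, with or without a role of Gata1, stays open, as does how many of these genes neurons also express.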
